A study of Mus musculus with 12 samples.

How the data were processed

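DNA of lineage-negative bone marrow progenitors was sequenced for 12 samples, 6 per genotype, in paired-end mode with 100 bp reads, per the labels' protocols. Each of 3 replicate numbers per genotype had 1 library from a bisulfite kit and 1 from an enzymatic conversion kit. The labels give both libraries of a number the same column name. Whether the reads of both kits were merged in that column is not given in the sources used here, and each kit alone was not analysed. The build was mm10, per the submitters' processing notes. The aligner and the methylation caller are not given in the sources used here.

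The authors deposited a table of methylation levels as a fraction between 0 and 1 for 107115 candidate regions in 6 columns, and lists of 35439 hypomethylated and 4 hypermethylated regions, whose rows repeat for each gene. Levels were multiplied to percent. Regions were called with metilene, per the file names. The deposited lists give a mean level per genotype as a fraction, the number of CpGs, the metilene q-value and the adjusted p-value of a further test that is not named. The deposited difference of means is a score, a difference between fractions. Tested on the files, listed regions had at least 10 CpGs, an absolute difference of at least 20 points and a further adjusted p-value of at most 0.0154, whereas the metilene q-value was not a filter. The authors' group means differed from the mean of the replicate columns by up to 8.40 points in the mutant and 9.08 points in the wild type, and 1445 candidate regions were lower by 20 points or more yet in neither list. Levels printed are means of the replicate columns. The numbers of CpGs are the authors'. No counts or coverage accompany the levels, so no coverage minimum was applied, the depth is unknown, and no interval for counting error is given. Candidate regions differ from regions never tabulated in ways that were not measured here.

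Columns were assigned to genotype by their names and the labels. No 2 replicate columns were alike: the smallest median absolute difference between columns was 2.44 points. The mean level over regions was compared with an exact two-sided permutation test. Each candidate region was tested with limma 3.58.1 in R 4.3.3 on the level in percent, with Benjamini-Hochberg adjustment and a threshold of 0.05. Simulated changes of 20 points in most of 107115 regions were recovered in 98.6%, with 3.78% of unchanged regions called. With only 100 regions changed by 20 points and 100 by 10 points, 23% and 0% were recovered.

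Gene positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 names. It matched 10704 of 12874 gene identifiers of the lists. That table has no strand, and no genome sequence was used here. Promoters (1 kb either side of the gene start) were therefore defined for the 8494 of 21883 protein-coding genes whose strand the deposited lists give, so counts at promoters cover those genes. Other regions that overlapped a protein-coding gene of the RefSeq table were called gene body. The rest were called intergenic and can overlap genes that are not protein-coding. The 11 gene lists were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. A list gene counted when a region overlapped its span plus 5 kb on each side. The plan was 5 kb upstream only, which needs strand. Counts were compared with 10000 random lists of protein-coding genes matched on span length in 20 bins, and median differences with 10000 random sets of regions, both two-sided with Benjamini-Hochberg adjustment over 11 lists. Genes and regions are not replicates, and neighbouring genes can share a region. On simulated lists the count test called 0 of 20 unrelated and 20 of 20 enriched lists, and the size test 1 of 20 unrelated and 20 of 20 shifted sets. The planned test of promoters against random positions was not run.

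The named regions were all hypermethylated regions, the 10 largest losses with a metilene q under 0.05, at least 10 CpGs and separated replicates, the same at promoters with 1 per gene, the 5 with the most CpGs, up to 4 members of each list by the largest loss with promoter regions first, and Dnmt1. Some regions that this rule took are not reported here. Differences are mutant minus wild type. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.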

Results

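Whole-genome methylation sequencing was compared between lineage-negative bone marrow progenitors of wild-type BALB/c mice and of mice carrying a mutation in Dnmt1, the enzyme that copies DNA methylation onto the new strand after replication. Lineage-negative cells are bone marrow cells depleted of those bearing markers of mature blood lineages, so that stem and progenitor cells are enriched. The labels write the mutant genotype as a knockout, whereas the series describes a missense mutation modelled on hypomorphic fish alleles that affect lymphoid development. The question was how far this mutation lowers methylation of the progenitor genome. The 12 samples comprised 6 of each genotype, made from 3 replicate numbers per genotype with 2 library kits, 1 based on bisulfite and 1 on enzymatic conversion. The deposited values held 1 column per genotype and replicate number, so each comparison rested on n = 3 against 3. Values were methylation levels of regions without read counts, and the depth behind each level is unknown. Nothing in the labels states that the replicates came from separate animals, so p-values measured only the spread between these samples.

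Methylation was lower in the Dnmt1 mutant at nearly every candidate region, including regions in genes of B cell (Pax5, Ebf1), T cell (Bcl11b, Thy1) and stem cell (Erg, Kit) identity. Over the 35439 regions that the authors listed as hypomethylated, the mean level was 48.4% ± 2.31 (SD, n = 3) in the mutant and 76.8% ± 0.334 (SD, n = 3) in the wild type. The difference was -28.4 percentage points, a relative change of -36.9%. Mutant replicates had mean levels of 46.1%, 48.4% and 50.7%, and wild-type replicates of 76.4%, 76.9% and 77.1%. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 allows. Over the 71672 candidate regions in neither list, the mutant mean was 66.5% ± 2.24 (SD, n = 3) and the wild-type mean 79.4% ± 0.368 (SD, n = 3), a difference of -12.9 points. The authors chose all of these regions on these same samples, so the size of the difference is not an independent estimate.

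**Figure D1:**
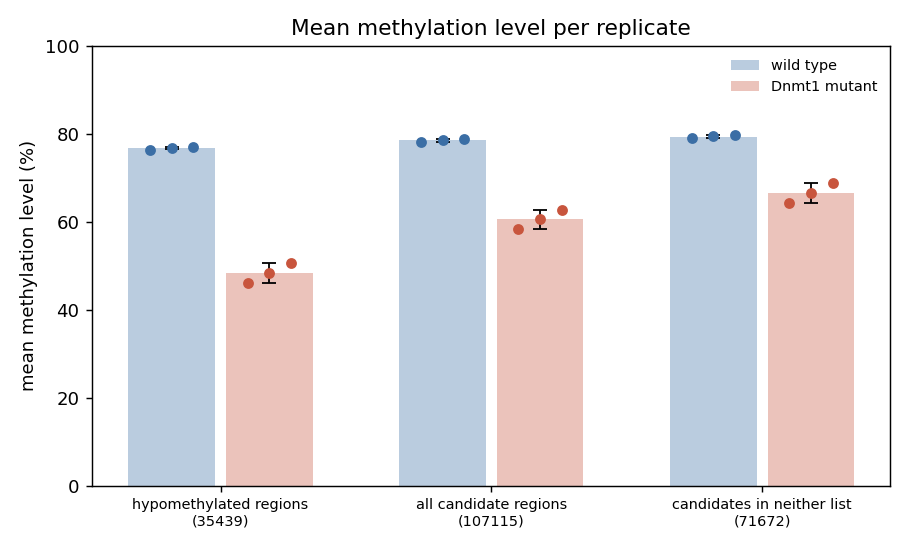
Mean methylation level in percent (vertical axis) of wild type (blue) and Dnmt1 mutant (red) over 3 sets of regions, whose numbers stand under each pair; bars show means, points the 3 replicates and error bars the SD. Mutant replicates lie between 46.1% and 50.7% over the hypomethylated regions and wild-type replicates between 76.4% and 77.1%.

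Region by region, calls in the mutant were almost all toward lower methylation. Of 107115 candidate regions, limma called 100125 lower and 52 higher in the mutant at an adjusted p under 0.05. Every mutant replicate lay below every wild-type replicate in 100959 candidate regions (94.3%) and above in 102. Chance gives 5% for each in regions not selected by the values, but the candidate regions were chosen for a difference on these same samples, so the separation is no test of it. Levels by position are given for the listed hypomethylated regions, each selected to be at least 20 points lower, so they describe those regions and not promoters or gene bodies in general. The 2123 hypomethylated regions within 1 kb of the start of a protein-coding gene had a mean level of 40.3% ± 2.20 in the mutant and 69.98% ± 0.386 in the wild type (SD, n = 3 each). In the 20039 regions in gene bodies the levels were 49.4% ± 2.38 and 77.5% ± 0.244, and in the 13277 intergenic regions 48.3% ± 2.21 and 76.8% ± 0.477 (SD, n = 3 each). Promoter regions lay at 2001 protein-coding genes. The median hypomethylated region was 720 bp long, held 12 CpGs and differed by -26.1 points (quartiles -31.8 and -22.7), and 675 regions were lower by 50 points or more. With a difference of at least 20 points also required, limma called 36772 regions lower and 4 higher. The count of higher regions was 30 without wild-type replicate 1 and 171 on a logit scale.

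Among listed regions with a metilene q under 0.05, at least 10 CpGs and separated replicates, the largest losses included regions of Apc2, Tfpt, Trim31 and Vtn. Losses of this size are possible only where the wild type is highly methylated. In Apc2, a relative of the tumour suppressor APC, a region of 60 CpGs on chromosome 10 (80312447 to 80313492, mm10) had a level of 9.43% ± 3.40 in the mutant and 88.3% ± 1.61 in the wild type (SD, n = 3 each). The largest difference under these limits, on chromosome 12 upstream of Gm5441 (117379582 to 117379790), had levels of 5.63% ± 0.932 and 85.3% ± 4.34. Vtn, which encodes the adhesive plasma protein vitronectin, had levels of 7.90% ± 0.861 in the mutant and 77.7% ± 3.39 in the wild type (chromosome 11, 78501645 to 78501904). Trim31, a ubiquitin ligase gene, had 3.94% ± 2.47 and 75.5% ± 2.46 (chromosome 17, 36909432 to 36909766). Regions of Cacnb4, a calcium channel subunit gene, the transcription factor gene Glis1, the ubiquitin ligase gene Lnx2 and 3425401B19Rik, and a region upstream of Gm14267, fell by 74.1, 72.7, 72.1, 70.4 and 73.7 points. Among the 72 lower regions taken by the rule for named genes, limma's adjusted p was at most 0.00198, which restates their selection and is no further evidence.

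At promoters, under the same limits and for genes whose strand was known, the largest loss was at Tfpt, which encodes a subunit of the INO80 chromatin remodelling complex (chromosome 7, 3628848 to 3629049), with levels of 10.6% ± 5.76 in the mutant and 87.3% ± 3.11 in the wild type (SD, n = 3 each). The promoter region of Pop5, an RNase P subunit gene, fell by 66.4 points, that of the urea transporter gene Slc14a1 by 65.9 points and that of Gpnmb by 65.6 points. At Proc, which encodes the anticoagulant protein C, levels were 5.33% ± 1.24 and 67.7% ± 5.05 (chromosome 18, 32139516 to 32139877). The promoter regions of Slc24a5, Zfp541, Ppp1r3d, Gas2l1 and Fbxo40 fell by 63.2, 62.5, 62.3, 62.0 and 61.0 points.

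The hypomethylated regions with the most CpGs lay in Elfn2, Lingo3, Rbmxl2, Jph2 and Jph3. Elfn2 held 142 CpGs in 1 region (chromosome 15, 78671759 to 78674948), with levels of 34.6% ± 16.7 in the mutant and 79.3% ± 6.16 in the wild type (SD, n = 3 each). Its mutant replicates spread from 15.4% to 45.5%. Lingo3 (138 CpGs) fell by 53.3 points and the germ cell RNA-binding gene Rbmxl2 (119 CpGs) by 42.9 points. The junctophilin gene Jph2 (112 CpGs) fell by 33.2 points, and the region shared by Jph3 and Gm20388 (100 CpGs) by 35.9 points.

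Dnmt1 itself had 5 hypomethylated regions in its span or within 5 kb of it, with differences from -32.8 to -20.7 points and none at the promoter. Averaged over these, the level was 49.6% ± 2.89 in the mutant and 74.3% ± 2.32 in the wild type (SD, n = 3 each). The region with the largest difference (chromosome 9, 20902140 to 20902845) had 16.7% ± 2.86 and 49.5% ± 2.55. These values do not show the mutation, since neither sequence nor expression was analysed here.

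Gain of methylation was rare and reached the authors' list at 4 regions. In Pde4d, a cyclic AMP phosphodiesterase gene, the level was 44.8% ± 8.80 in the mutant and 18.6% ± 2.17 in the wild type (SD, n = 3 each; chromosome 13, 109116425 to 109116578), a difference of 26.1 points with a limma adjusted p of 0.000383. A region overlapping Coro7, Vasn and Dnaja3 (chromosome 16, 4640264 to 4640496) had 60.1% ± 8.45 and 36.6% ± 12.5. C530008M17Rik (chromosome 5, 76857151 to 76857356) had 51.2% ± 14.3 and 22.6% ± 12.8. The region shared by Nradd and Nbeal2 (chromosome 9, 110624291 to 110624831) had 70.7% ± 4.74 and 48.4% ± 15.6. In the authors' deposited table only the Pde4d region had a metilene q under 0.05 (q = 0.00021), and of the listed hypomethylated regions 8272 did.

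Most lymphoid genes with a candidate region had a region called lower, but candidate regions were chosen for a difference. Of the lymphoid priming and B lineage regions 168 of 185 were called lower, and of the T and NK lineage regions 122 of 134. The share over all candidate regions was 100125 of 107115, so these calls are not particular to lymphoid genes. In the list of lymphoid priming and B lineage genes, 22 of 28 members had a candidate region, 21 had 1 called lower by limma and 0 had 1 called higher. Pax5, the regulator of B cell commitment, held 34 hypomethylated regions within its span on chromosome 4 (44524748 to 44710694) or 5 kb to either side, the window used for all list genes, with a mean level of 46.4% ± 1.95 in the mutant and 75.7% ± 0.477 in the wild type (SD, n = 3 each). A region at the promoter of Ikzf1, which encodes the lymphoid regulator Ikaros, had 6.52% ± 4.12 and 38.5% ± 2.35 (chromosome 11, 11685012 to 11685191). Promoter regions of Irf8 and Ccr7 fell by 28.5 and 21.2 points. A region in the B cell regulator Ebf1 fell by 46.3 points, where the median of its 4 regions was -27.5 points. A lower region named for a list gene, here and below, is that of largest loss, with promoter regions taken first. Among T and NK lineage genes, 16 of 20 members had a candidate region and 16 had a region called lower. Bcl11b, a T cell commitment factor, held 21 hypomethylated regions with means of 46.3% ± 0.958 and 76.5% ± 0.406 (SD, n = 3 each), and its largest loss was -56.5 points. A region at Thy1, a T cell surface glycoprotein gene, fell by 53.5 points, and the promoter regions of Lck and Cd8a fell by 23.6 and 22.9 points.

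**Figure D2:**
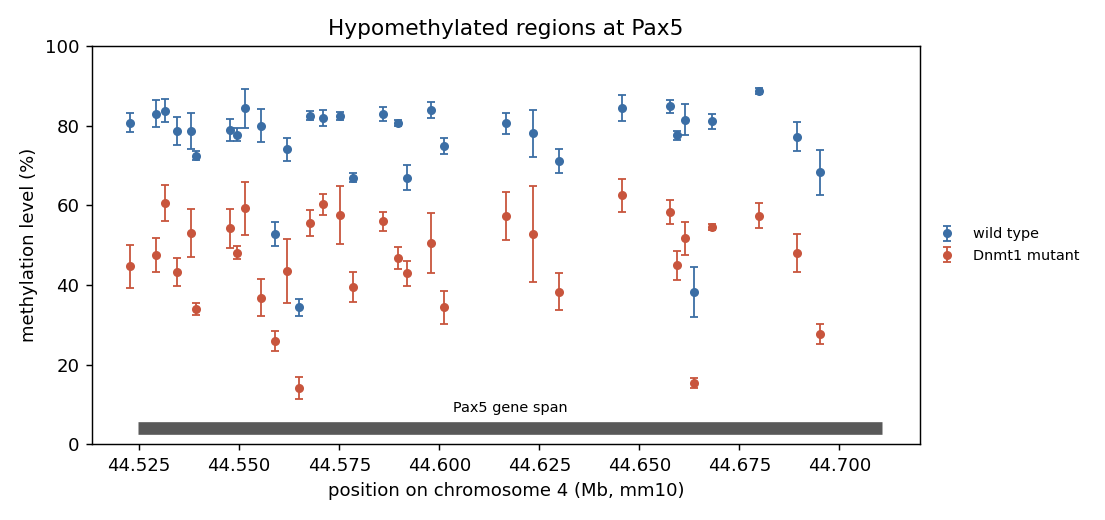
Methylation level in percent (vertical axis) of the 34 hypomethylated regions in or within 5 kb of Pax5 by position on chromosome 4 in Mb (horizontal axis, mm10); points show means of 3 replicates and error bars the SD, with wild type in blue, Dnmt1 mutant in red and the gene span as a grey bar. Differences range from -43.1 to -20.2 points.

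Lower regions were also called at genes of the other blood lineages, with candidate regions chosen for a difference. Of the granulocyte and monocyte genes, 17 of 20 had a candidate region and 16 a region called lower. Promoter regions of Camp, which encodes an antimicrobial peptide of neutrophils, of the granulocyte regulator Cebpe, of Csf2ra and of Ngp fell by 31.9, 30.5, 30.3 and 24.5 points. Of the erythroid and megakaryocyte genes, 12 of 20 had a candidate region and 11 a region called lower. Slc4a1, the red cell anion exchanger gene, held 8 hypomethylated regions with means of 41.5% ± 3.27 in the mutant and 74.9% ± 1.24 in the wild type (SD, n = 3 each). Regions at the globin gene Hba-a1, the platelet adhesion gene Vwf and the promoter of Gp1ba fell by 42.5, 37.1 and 25.4 points. Of the stem and multipotent progenitor genes, 18 of 20 had a candidate region and 17 a region called lower. The largest losses at Erg and the receptor gene Kit were 47.6 and 31.4 points. The medians were -21.1 points over 7 regions at Erg and -26.7 over 2 at Kit. The promoter region of Pdzk1ip1 fell by 27.2 points. Of the stromal and endothelial genes, which mark other cells of the marrow, 11 of 15 had a candidate region and 11 a region called lower. A region of the collagen gene Col1a1 fell by 60.3 points, where the median of its 8 regions was -27.1 points. Promoter regions of Cdh5, Pecam1 and Sp7 fell by 25.5, 23.2 and 20.4 points.

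Imprinted genes, which are methylated on 1 parental allele, had regions called in both directions. Candidate regions lay at 23 of 25 members, and limma called 161 of these 221 regions lower and 5 higher. The promoter region of the growth inhibitor gene Cdkn1c fell by 35.2 points, those of Magel2 and Nnat by 30.3 and 27.3 points, and a region at Igf2 by 40.5 points. The 5 higher regions lay at Grb10, at Igf2r and Airn, at Gnas (2 regions) and at Inpp5f, and were singled out after their values were seen. The call was lost in 4 of 9 alternative limma fits at Grb10, at Igf2r and Airn and at 1 Gnas region, and in 3 at the other Gnas region. Their differences were 13.2, 7, 12.4 and 11.3 points, and replicates of the groups overlapped at Grb10 and at the Gnas region with 12.4 points. The region at Inpp5f was called in all 9 alternative fits. At Inpp5f (chromosome 7, 128687882 to 128688027) the level was 57.2% ± 6.80 in the mutant and 39.0% ± 8.43 in the wild type (SD, n = 3 each), with a limma adjusted p of 0.00523. Of the germline genes, 19 of 21 had a candidate region and 19 a region called lower. Promoter losses were -40.2 points at the piRNA pathway gene Tdrd1, -35.5 at Tex19.1, -33.5 at the meiosis gene Syce1 and -31.9 at Mael. Of the genes of the DNA methylation and silencing machinery, 17 of 22 had a candidate region and 17 a region called lower. Regions at Mbd2, Ehmt2 and the methyltransferase gene Dnmt3a fell by 52.3, 44.3 and 38.4 points. Of the Hox and developmental transcription factors, 25 of 26 had a candidate region and 19 a region called lower, and 3 shared a single higher region in the Hoxa cluster. In this list 73 of 120 candidate regions were called lower, against 100125 of 107115 over all candidate regions. Regions at Tbx5, Pax2 and Nkx2-2 fell by 60.6, 43.1 and 42.9 points, and the promoter region of Hoxb4 by 20.8 points. Of the interferon and viral sensing genes, 13 of 20 had a candidate region and 13 a region called lower. Regions at Ifih1 and the promoters of Irf7 and Mavs fell by 52.1, 31 and 28.4 points. Over the 1353 candidate regions at genes of the 11 lists, limma called 1156 lower and 6 higher with adjustment over all regions, and 1147 lower and 6 higher adjusted over the list alone.

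Granulocyte and monocyte genes held a listed hypomethylated region more often than genes of like length, at 15 of 20 members against 8.05 in random lists (permutation test, adjusted p = 0.0330). Random lists were matched on length and not on holding a candidate region, as 17 of the 20 members did. The excess can therefore reflect where regions were tabulated, and the same limit holds for the other list counts. Of the 85 candidate regions at granulocyte and monocyte genes, limma called 70 lower, against 100125 of 107115 over all candidate regions. Elane and Prtn3 are neighbours in the granulocyte and monocyte list and shared 2 of the regions. This call was lost with autosomal genes only (15 members against 8.79, adjusted p = 0.0506), with the gene span alone (11 against 5.79, adjusted p = 0.132) and with a metilene q under 0.001 (2 against 2.18, adjusted p = 1). T and NK lineage genes had 14 of 20 against 8.96 (adjusted p = 0.152), which passed with q under 0.001 (adjusted p = 0.0352) and with the gene span alone (adjusted p = 0.0308). The Hox and developmental genes had 5 of 26 against 10.98 (adjusted p = 0.106). The others had 15 of 28 against 12.6 for lymphoid priming and B lineage, 9 of 20 against 9.54 for stem and multipotent progenitor, 9 of 20 against 7.45 for erythroid and megakaryocyte and 8 of 15 against 6.84 for stromal and endothelial genes. They had 12 of 21 against 9.16 for imprinted, 8 of 21 against 9.68 for germline, 10 of 22 against 10.3 for methylation machinery and 9 of 18 against 7.79 for interferon genes, with adjusted p of at least 0.807 for all 8 lists not named before. For the size of the difference within hypomethylated regions, 0 of 11 lists passed the permutation test after adjustment, and 4 had an unadjusted p under 0.05. Among these 4, only the Hox and developmental genes lost more than random sets. Medians were smaller losses for stem and multipotent progenitor (-23.9 against -26.2 points), methylation machinery (-23.1 against -26.3) and interferon genes (-22.7 against -26.4). The lowest adjusted p was 0.0638, for the Hox and developmental genes (median -32.6 points against -26.3, with 15 of the 20 regions at Pax2 and Tbx5). That gap rested on mutant replicate 3, without which the medians were -28.9 and -27.7 points (adjusted p = 0.826). Without mutant replicate 1, 3 lists passed. Hox and developmental genes lost more than random sets (-32.6 against -25.3 points, adjusted p = 0.0253). Methylation machinery (-21.3 against -25.2) and granulocyte and monocyte genes (-21.8 against -25.2) lost less.

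**Figure D3:**
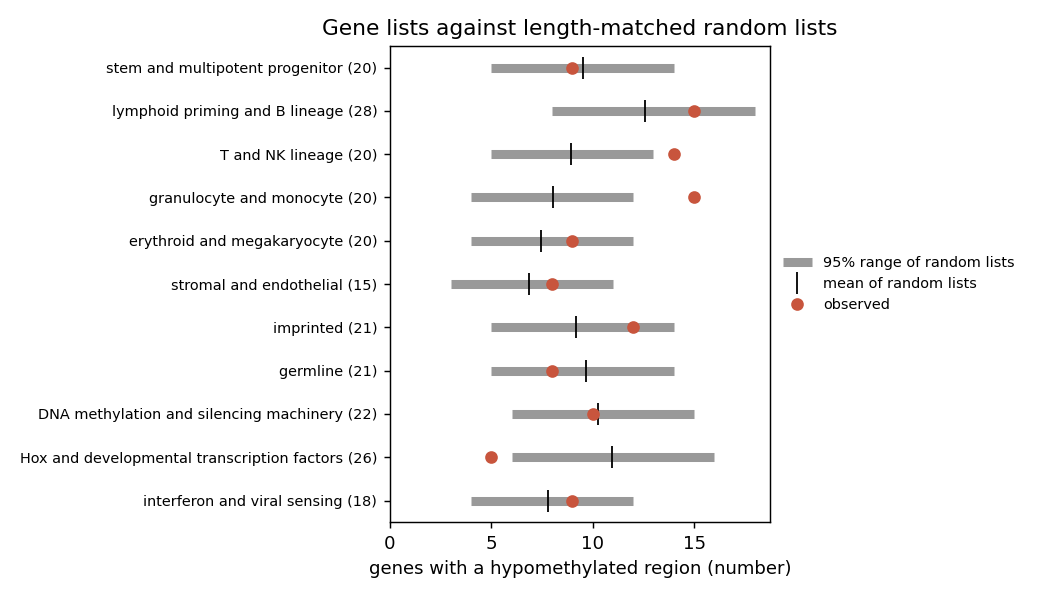
Number of genes with a hypomethylated region (horizontal axis) in each of 11 gene lists, whose tested sizes stand in brackets; red points show the observed number, black marks the mean and grey bars the 95% range of 10000 random lists matched on gene length. The granulocyte and monocyte list, with 15 genes against 8.05, is the 1 list that passed after adjustment.

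Hypomethylated regions were spread over every autosome and were scarce on the sex chromosomes. Chromosome 11 had 27.4 hypomethylated and 75.1 candidate regions per Mb, and chromosome 3 had 5.99 and 21.4. The X chromosome had 28 hypomethylated regions, or 0.164 per Mb, and the Y chromosome 10. Candidate regions were as scarce there, at 92 on X and 26 on Y, so methylation of most X-linked genes was not measured in these values.

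**Figure D4:**
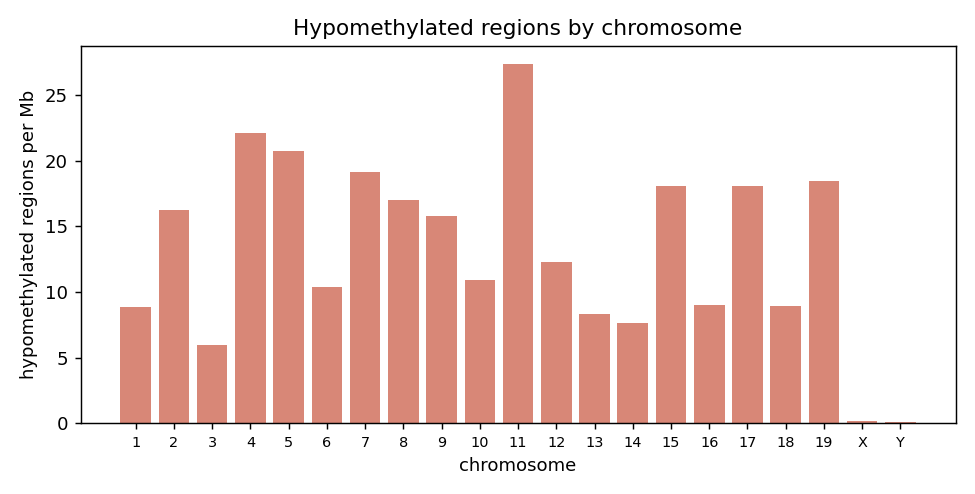
Hypomethylated regions per Mb (vertical axis) on each chromosome (horizontal axis), counted to the end of the last annotated gene. Chromosome 11 has the highest value, 27.4 per Mb, and X has 0.164.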

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

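Metilene q under 0.05, the gene span alone and autosomal genes only (for list counts) were chosen after seeing the data. The lower mean level in the mutant kept its direction under all 12 alternatives and moved past the replicate spread under 1, metilene q under 0.001, with -36.3 points. That alternative keeps regions with larger differences. All regions averaged here were listed for a loss of at least 20 points on these same samples, so the kept direction is no further evidence. Requiring a difference of 20 points left 36772 lower and 4 higher regions. Higher regions numbered 171 on a logit scale and 30 to 63 without 1 replicate, and the cause was not tested. A metilene q under 0.05 left 8272 hypomethylated and 1 hypermethylated region. For list counts, 0 lists passed with autosomal genes only, and the granulocyte and monocyte excess over random lists turned to -0.18 genes with q under 0.001. For list sizes, 0 to 3 lists passed without 1 replicate. The cause was not tested. All 76 regions taken by the rule for named genes kept direction and call in 9 alternative limma fits, with adjusted p up to 0.0473. They too were selected on these same samples, so this is no independent evidence.

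Same-numbered replicates did not deviate together (correlations across regions 0.0372, 0.0049 and 0.050, where 0.1 was required), although 5 of 6 correlated best with their own number, a hint from the data only. With the replicate number as a block, limma called 99903 regions lower and 70 higher, and the mean difference was -28.4 points (exact sign-flip p = 0.25, the smallest that 3 pairs give). The 6 replicates make 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 100125 lower and 52 higher regions, and the highest count in another split was 0 for both. Not run were each kit alone, the promoter tests and the promoter window for lists, matching on CpGs, which need strand or sequence, and a minimum of 20 CpGs for limma, since CpG numbers accompany the listed regions only. Depth is unknown, so its limits could not be assessed.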

Other observations

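All tests in this part were chosen after the values were seen. Large gene families differed in how often their members held a hypomethylated region within 5 kb, against random genes of like length. Random genes were not matched on candidate regions, CpGs or mapping. The shares can therefore reflect where regions were tabulated and need not concern the size of the loss. Olfactory receptor genes (Olfr) did so in 5.14% against 16.7%, vomeronasal receptor genes (Vmn) in 3.10% against 23.3%, and genes named Zfp in 23.2% against 45.3%. Protocadherin genes (Pcdh) did so in 85.5% against 48.3%, potassium channel genes (Kcn) in 71.3% against 47.4%, calcium channel genes (Cacna and Cacng) in 86.4% against 50.6%, keratin genes (Krt) in 45.5% against 27.7%, collagen genes (Col) in 70.5% against 50.5% and solute carriers (Slc) in 60% against 45.8%. These 9 of 13 families had a permutation adjusted p under 0.05, but members lie in clusters and share regions, so the p-values are too small. Ribosomal protein, Cd, proteasome and Cyp genes did not pass. Rbfox3, a neuronal splicing factor gene, held 124 hypomethylated regions over a span of 422 kb and Camta1 113 over 802 kb. Cux2 held 65 over 192 kb, Zfp469 63 over 230 kb and Cdh4 60 over 457 kb. These counts were not adjusted for gene length.

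Across the 19 autosomes, hypomethylated regions per Mb rose with protein-coding genes per Mb (Pearson r = 0.759, permutation p = 6.0e-05; Spearman rho = 0.791, permutation p = 9.0e-05; r = 0.697 without chromosomes 11 and 7). It was the 1 such relation computed, and chromosomes are not replicates. Candidate regions per Mb also ran from 21.4 on chromosome 3 to 75.1 on chromosome 11. The relation can therefore reflect where regions were tabulated and need not concern the size of the loss. The mitochondrial genome had 5 candidate regions with 41.1% ± 4.16 in the mutant and 47.2% ± 2.82 in the wild type (SD, n = 3 each, exact permutation p = 0.2). Of them, 0 were in the lists. Conversion, depth and mapping were not assessed for these regions, so their levels do not show that mitochondrial DNA is methylated.

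Candidate regions at imprinted genes, and also at Hox and developmental genes, lost less methylation than others of the same wild-type level. The draws took regions independently, whereas regions of a list lie close together at few genes, so the permutation p-values given here are too small. Leaving out 1 gene was done for the imprinted genes only. The 120 Hox and developmental regions had a median of -7.08 points against -10.7 in level-matched draws (permutation adjusted p = 0.0011), and the 7 of these with 30 to 70% methylation in the wild type -11.9 against -21.5 (adjusted p = 0.0462). Of the lists that did not pass at 30 to 70%, all but interferon and viral sensing genes (-31.5 against -22.1) also lost less than their draws. Stem and multipotent progenitor genes had -18.2 against -23.8 points (permutation adjusted p = 0.0543). The 78 imprinted regions with 30 to 70% in the wild type, at 19 genes, had a median of -8.76 points. Losses were larger at Cdkn1c (median -35.2) and Magel2 (-27.04 at 1 region). Random candidate regions of the same level had -24.9 points (95% range -27.6 to -22.3, permutation adjusted p over 11 lists 0.0022, from the smallest p the draws can give). Those of the same level and length had -27.2 points, which argues against mean level or length as the whole cause. Without any 1 gene the median was between -9.70 and -8.59 points, so no single gene accounted for it, and 5 of the 221 imprinted regions were called higher where level-matched draws gave 0.127. The draws matched the level averaged over both alleles, and alleles were not told apart. A region methylated on 1 allele alone can have the same mean as a region partly methylated on both. Candidate regions at 90 to 100% in the wild type had a mean difference of -13.0 points. The draws therefore cannot decide whether methylation of 1 allele accounts for the smaller loss. Maintenance of imprinted marks that is less sensitive to this mutation is a further hypothesis. No biological explanation was tested, CpG density was not measured, and 4 of the 5 higher regions lost their call in at least 3 of 9 alternative fits.

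Regions were scarce on the X chromosome, with 0.539 candidate regions per Mb against 21.4 to 75.1 on autosomes. A coverage minimum that a chromosome carried once in males rarely meets may be the cause: 24 of the 92 candidate regions (26.1%, exact binomial 95% interval 17.5 to 36.3%) lay from the start of Mid1 on, a stretch of 0.582% of the chromosome that includes the segment shared by X and Y. The labels give no sex and other filtering by the authors was not tested, so this stays a hypothesis. The share of CpGs counted as missing had a median of 5.88% in the 21 X regions before Mid1 and 6.45% on autosomes (permutation p = 0.901), which decides nothing. A smaller loss on X cannot be told apart from these, because the regions were picked for a difference: X candidate regions had a median of -15.5 points and autosomal ones -16.6.

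Above a wild-type level of 10%, the share of methylation kept in the mutant was smaller where the wild type was less methylated: 86.0% at 90 to 100% wild-type level, 57.6% at 60 to 70% and 36.2% at 10 to 20%. The trend did not extend to the 4517 regions at 0 to 10%, where 40.7% was kept. Sorting on 1 wild-type replicate and measuring on the other 2 left a difference of at least 48.0 points between the top bin and the 10 to 20% bin, which argues against regression to the mean. From 60% up, the loss grew as the level fell, from -13.0 ± 2.42 points at 90 to 100% to -27.8 ± 2.09 at 60 to 70% (SD of the mutant, n = 3). The growth was at least 14.4 points in each mutant replicate. A single minimum difference in points at every level would not by itself produce it. The 5th percentile of the loss also grew, from 5.90 in the top bin to 12.4 at 60 to 70%. Selection with a minimum that differs by level was therefore not excluded. Below 60% the loss in points shrank again, to -9.31 at 10 to 20%, where the 5th percentile was 4.52 against 5.90 in the top bin. Selection may contribute there too and stays open, and no biological explanation was tested.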
